A study of Homo sapiens with 6 samples.

How the data were processed

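Total RNA from UM-UC-3 cells was made into libraries with an Illumina TruSeq kit after lipid-mediated transfection with empty vector or with a pcDNA3.1 plasmid carrying circNCOR1, per the labels' protocols. There were 3 libraries per group, grouped by the transfected plasmid that the labels name. HISAT2 2.0.4 and the hg38 genome build are named in the submitters' processing notes. The counting tool, gene annotation, strand setting and treatment of reads shared between genes are not given in the sources used here, so near-identical, overlapping and antisense genes are reported as uncertain.

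The deposited table holds, per the file headers, a count and an FPKM for each gene and library. The deposited counts were treated as estimated counts, because 11.4% to 12.4% of values per library differed from a whole number by more than 0.005. They were not scaled, and they were rounded to whole numbers before testing. The FPKM values deposited by the authors, fragments scaled to transcript length and library size, served only for an alternative test and for the transcript length that a gene's count and FPKM imply. The count and FPKM columns, 6 of each, were matched to samples by name, and no other column of per-sample values was present. Of 20289 genes, 3138 had no count in any library. GENCODE release 29 supplied positions, and 20171 gene identifiers (99.4%) matched it. Its GRCh38 build is the one that hg38 names.

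Differential expression was tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr at its defaults (a count minimum of 10 and a total of 15), and the robust quasi-likelihood F test with group as the only term. P-values were adjusted by Benjamini-Hochberg over the 13303 genes tested, with a threshold of 0.05. The biological coefficient of variation was 6.08%, and depths were 15681700 to 22119800 estimated counts per library. Gene lists, 44 in all, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over lists, with an estimated correlation and with fry beside it. Terms of 10 to 500 tested genes were tested with a one-sided Fisher's exact test against all tested genes. Genes with 1 to 3 vector counts are given as a ratio of summed counts with an exact 95% binomial interval, and a gene with none against a floor of 3 counts over the group.

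The groups, the main test, the gene lists, the rule for named genes and all alternatives except those named as later were fixed before the data were examined. The rule took 12 genes regardless of outcome, the 10 largest changes each way among called genes with a symbol, a mean of at least 1 CPM and non-overlapping groups, and the 3 members of each list with the smallest p among those that passed, and not every gene it took is printed. DDX58, IFIH1, MMP9 and the members that moved against their list (EGR1, CTH, SLC7A5, DDIT4, CASP9, BMF, PDGFA, VEGFB, CYCS, NDUFA4, HK2, SLC16A3, ITGA1, ITGA2, BCAR1, KRT5 and EGFR) were named after their values were seen, as were the genes singled out in the other observations.

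The procedure was tested on simulated data for this comparison, 10 simulations of 13303 genes with 200 genes changed in each. It recovered 30% of genes changed 1.2-fold, 75.6% at 1.5-fold, 89.0% at 2-fold and 97.8% at 4-fold. Of its calls 8.78% were of unchanged genes (6.10% to 11.5% per simulation), above the nominal 5%. Calls near the threshold may therefore be less certain than their adjusted p. Far fewer genes were changed in the simulations than the 6445 called in the data. The recovery and the share of unchanged genes depend on that fraction and need not carry over. Camera called the shifted list in 10 of 10 simulations and 0 of 400 unshifted lists. Every member of the shifted list was moved by the same amount, and smaller or mixed shifts were not simulated. The 10 of 10 therefore does not show how often such shifts would be called. The simulated genes varied independently of each other, so the 0 does not show how often camera calls an unshifted list of correlated genes.

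Replicates of one group differed by more than sampling noise (chi-square over degrees of freedom 2.26 to 9.34, highest for circNCOR1 replicate 1), so none was treated as one library deposited again. The sources describe independent experiments without saying how they were divided, so p-values measure the spread between these libraries. The alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters on low counts, removal of mitochondrially encoded genes, a replicate block and each library left out in turn. A limma test of log2(FPKM + 1) for genes with a mean FPKM of at least 1, a test against a 1.2-fold change and lists without NCOR1 were chosen after seeing the data, as were the tests of leukocyte transcripts and of the G1/S list as explanations.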

Results

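RNA sequencing measured gene expression in UM-UC-3 cells, an established human bladder cancer line, after transfection with an empty vector plasmid (3 libraries) or with a plasmid carrying circNCOR1 (3 libraries). A circular RNA is a closed transcript made by joining the end of an exon back to an upstream exon, and circNCOR1 takes its name from NCOR1, which encodes a nuclear receptor corepressor. The series describes 3 independent experiments and places the comparison in a study of lymph node spread of bladder cancer. Estimated counts summed, rounded, to 19405900, 21558700 and 16598400 in vector replicates 1, 2 and 3, and to 22119800, 16236600 and 15681700 in circNCOR1 replicates 1, 2 and 3. Of 20289 genes in the table, 13303 had enough counts to be tested. Values below are TMM-scaled CPM (counts relative to the library total) as mean ± SD with n = 3 per group, folds are circNCOR1 over vector unless a gene is called lower, and positions are those of GENCODE release 29 on GRCh38.

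The comparison asked which genes differ in expression once circNCOR1 is overexpressed. Interferon and antiviral genes were prominent among the largest increases: IFNL1, a secreted type III interferon, went from 0.182 ± 0.14 to 48.1 ± 1.6 CPM, and IFNB1, a type I interferon, from 0.0847 ± 0.049 to 9.74 ± 1.2 CPM. All 37 genes of the type I interferon response list rose, with a median log2 fold change of 2.74. Inflammatory cytokine genes, MHC class I genes, p53 targets and ribosome biogenesis genes were also mostly higher. Mitotic genes, mitochondrially encoded genes and cytosolic ribosomal protein genes were mostly lower.

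The libraries separated by group. Spearman correlations across genes were 0.995 to 0.997 between libraries of one group and 0.977 to 0.980 between groups, and the first dimension of a multidimensional scaling held 63.2% of the variation. Within groups, circNCOR1 replicate 1 stood apart in its counts, with a chi-square over degrees of freedom of 9.34 and 8.16 against the other circNCOR1 libraries, where the other pairs of 1 group gave 2.26 to 3.23. In edgeR's quasi-likelihood test, 6445 of 13303 genes (48.4%) passed a Benjamini-Hochberg adjusted p of 0.05, 3386 higher and 3059 lower in the circNCOR1 libraries. Many of these changes were small: 1764 of the called genes changed by less than 1.2-fold, and 662 changed by at least 2-fold, 495 higher and 167 lower. The 3 libraries of one group lay wholly above those of the other in 57.4% of tested genes, where chance gives 10%. The median log2 fold change of all tested genes was 0.01. Without circNCOR1 replicate 1, 6951 genes passed, 3455 higher and 3496 lower, and 720 changed by at least 2-fold. In a test against a 1.2-fold change, chosen after seeing the data, 2637 genes passed.

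**Figure D1:**
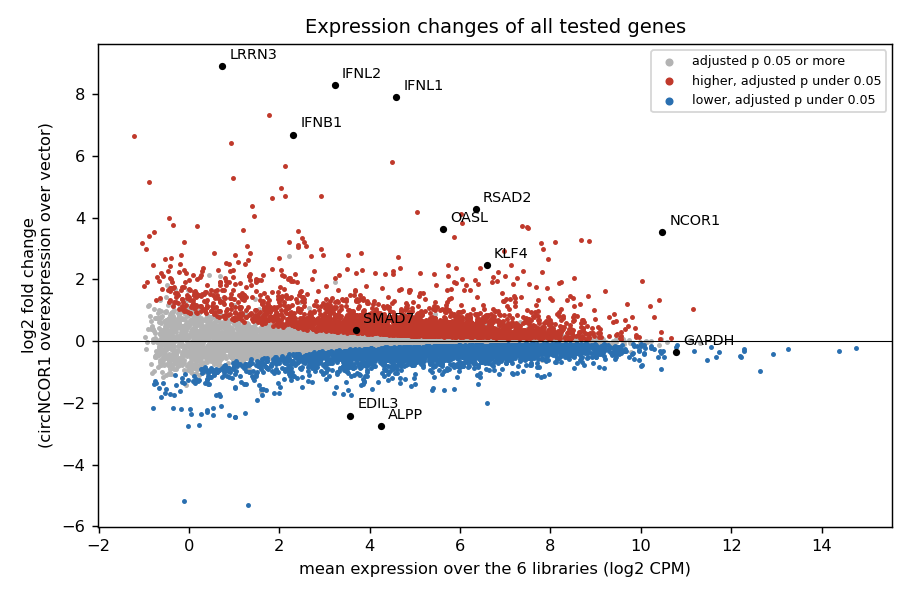
Each point is 1 of 13303 tested genes, with mean expression in log2 CPM on the horizontal axis and the log2 fold change of circNCOR1 overexpression over vector on the vertical axis; red genes were higher and blue genes lower at an adjusted p under 0.05, and black points are named genes. LRRN3 had no vector counts, so its height is a fitted value and not a measured fold.

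Reads assigned to NCOR1 (ENSG00000141027, chromosome 17, 16029157 to 16218185, minus strand) rose 11.5-fold, from 229 ± 2.1 to 2623 ± 125 CPM (log2 fold change 3.52, SE 0.04, edgeR adjusted p = 1.9e-17). The table counts reads per gene, and no entry in it was matched to the circle, so no circNCOR1 level is given. Any reads from the circle, from linear RNA made by the plasmid and from the chromosomal gene would be counted together under NCOR1, in shares that are not known.

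Among the genes named in advance for the TGF-beta pathway, the inhibitory SMAD7 (ENSG00000101665, chromosome 18, 48919853 to 48952052, minus strand) rose 1.27-fold, from 11.4 ± 0.50 to 14.5 ± 1.4 CPM (SE 0.10 on a log2 change of 0.35, edgeR adjusted p = 0.013). The SMAD7 call ended without circNCOR1 replicate 2 (adjusted p = 0.068), in DESeq2, in a limma test of FPKM (0.063 in both) and in a test against a 1.2-fold change, within a range of 0.0066 to 0.26 over all alternatives. SMAD2, a receptor-activated SMAD, was 1.27-fold lower, at 71.8 ± 4.9 against 90.8 ± 4.0 CPM (edgeR adjusted p = 0.00020), and it passed under every alternative except the test against a 1.2-fold change. TGFBR2, a TGF-beta receptor subunit, was lower by a log2 change of -0.11 (edgeR adjusted p = 0.034). The TGFBR2 call ended under total-count scaling, in DESeq2 and when any 1 library other than circNCOR1 replicate 1 was left out (up to adjusted p = 0.10), in 10 of 17 alternatives in all, with a range of 0.014 to 1.0 over all alternatives. SMAD3 (589 ± 24 against 583 ± 27 CPM), SMAD4 (104 ± 6.4 against 103 ± 4.9), TGFB1 (66.0 ± 3.2 against 68.8 ± 1.7), TGFBR1 (113 ± 9.6 against 122 ± 6.9) and the RNA-binding protein gene HNRNPL (233 ± 6.6 against 237 ± 6.8) did not pass, vector first. Of 27 measured TGF-beta and SMAD pathway components, 9 rose, 8 fell and 10 did not pass, with 18 past the threshold adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.87). The Gene Ontology term for transforming growth factor beta receptor signaling was enriched among lower genes, with 30 of 79 where 18.2 would be expected (Fisher's exact test, adjusted p = 0.042). LTBP2, named for the latent TGF-beta binding protein family, rose 1.83-fold. SMURF1, a ubiquitin ligase acting on SMADs, rose 1.35-fold, whereas the BMP receptor BMPR1A was 1.35-fold lower.

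Of 29 TGF-beta-induced target genes, 16 rose, 9 fell and 4 did not pass, and 26 passed adjusted over the list alone. CCN1, a matricellular protein gene, rose 2.07-fold and KLF10 by a log2 change of 0.67, while ID1, an inhibitor of basic helix-loop-helix factors, was 2.88-fold lower. The list had a median log2 fold change of 0.35 and did not pass (camera adjusted p = 0.058), although it did under some other settings, among them without vector replicate 2 (adjusted p = 0.043) and in DESeq2 (adjusted p = 0.045), with a range of 0.039 to 0.075.

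VEGFC, a growth factor for lymphatic vessels (chromosome 4, 176683538 to 176792727, minus strand), rose 1.95-fold, from 25.4 ± 1.7 to 49.4 ± 2.2 CPM (edgeR adjusted p = 3.9e-08). Of 23 measured lymphangiogenesis and angiogenesis factors, 15 rose, 2 fell and 6 did not pass, with 18 past the threshold adjusted over the list alone (camera adjusted p = 0.00034, and adjusted p = 0.12 with an estimated correlation). ANGPTL4 rose 3.17-fold and the chemokine gene CXCL8 2.22-fold. The 2 that fell were PDGFA, 1.62-fold lower, and VEGFB, 1.26-fold lower. The VEGFB call ended without circNCOR1 replicate 2 (adjusted p = 0.061) and in the test against a 1.2-fold change (range 0.0058 to 0.31). Among genes changed at least 2-fold, the Gene Ontology term for angiogenesis was enriched in both directions. It held 19 higher genes of 195, where 7.26 would be expected, and 9 lower, where 2.45 would be expected (one-sided Fisher's exact test, adjusted p = 0.0081 and 0.037).

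**Figure D2:**
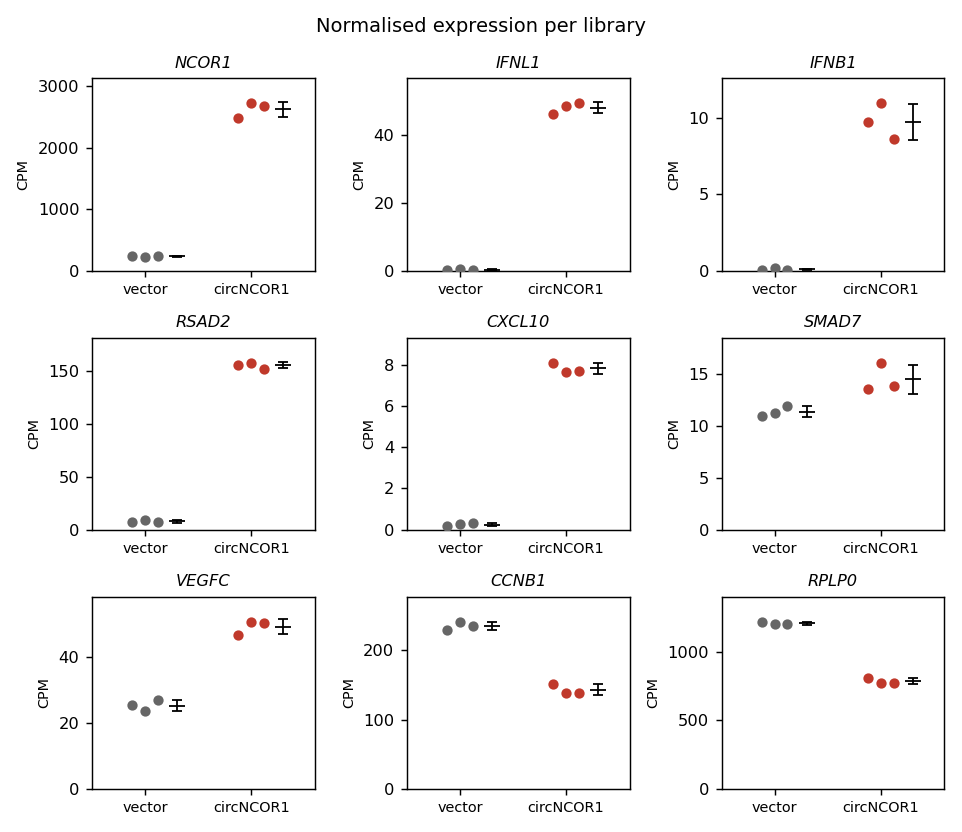
Normalised CPM of 9 genes in each of the 6 libraries (dots), with the group mean and SD beside them (middle line and bar, n = 3); each vertical axis starts at 0. The NCOR1, IFNL1, IFNB1, RSAD2, CXCL10, SMAD7 and VEGFC dots of the circNCOR1 group lie above those of the vector group, and the CCNB1 and RPLP0 dots below.

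Among genes with a symbol, a mean of at least 1 CPM and non-overlapping groups, those with the largest increases were mostly interferons and antiviral genes. IFNL1 (chromosome 19, 39296325 to 39298673, plus strand) rose 240-fold (log2 fold change 7.91, and 8.65 without vector replicate 2, which held 7 of its vector counts) and IFNB1 (chromosome 9, 21077105 to 21077963, minus strand) 103-fold. IFNL2 had 3 vector counts in all, giving a ratio of 354 with a 95% exact counting interval of 121 to 1718, and IFNL3 had 2 vector counts, giving a ratio of 191 (52.6 to 1585). Of these vector counts, vector replicate 3 held 2 for IFNL2 and both for IFNL3, so that without it 1 and none remained. The fitted log2 fold change of IFNL3, 7.33, was 6.73 without vector replicate 2. IFNL2 and IFNL3 are near-identical copies, so the division of reads between them is uncertain. IFI44L rose 56.0-fold, CXCL10, a chemokine that draws T cells, 30.9-fold, and CH25H, which makes 25-hydroxycholesterol, 51.3-fold. Vector replicate 1 held 7 of the vector counts of CH25H, whose log2 fold change of 5.68 became 7.14 without it. Outside this group, LRRN3, a leucine-rich repeat protein gene, had no vector count and 3.27 ± 0.95 CPM in the circNCOR1 libraries, at least 59.6-fold higher against a floor of 3 counts over the vector group. The sodium channel gene SCN3A had 2 vector counts and a ratio of 102 (28.0 to 851), and the basal keratin gene KRT14 rose 39.1-fold to 3.69 ± 0.40 CPM (log2 fold change 5.29, and 5.95 without vector replicate 1). Counting intervals and floors cover counting error only.

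Among genes chosen in the same way, the largest decreases were smaller. ALPP, placental alkaline phosphatase (chromosome 2, 232378534 to 232382889, plus strand), was 6.71-fold lower, at 4.86 ± 0.51 against 32.9 ± 4.2 CPM, and its close copy ALPG was 5.24-fold lower, with reads that may be divided uncertainly between them. EDIL3, an extracellular matrix protein gene, was 5.33-fold lower (19.7 ± 0.35 against 3.66 ± 0.65 CPM). ZNF608, SLC12A8, ADCY5, AOC1, FAT3, OLFML2B and CAPN14 were 4.96-fold to 6.55-fold lower, from vector levels of 1.81 to 3.73 CPM.

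Among interferon response genes, RSAD2, an antiviral enzyme, rose 19.5-fold, from 7.89 ± 1.2 to 155 ± 2.8 CPM, CMPK2 rose 14.3-fold and OASL 12.4-fold. The cytosolic RNA sensor genes DDX58 (RIG-I) and IFIH1 (MDA5) rose 4.12-fold and 5.49-fold. All 37 measured genes rose, and 37 passed adjusted over the list alone (camera adjusted p = 6.0e-33, and adjusted p = 0.12 with an estimated correlation). Of 29 NF-kappa-B and inflammatory cytokine genes, 24 rose, none fell and 5 did not pass, with 25 adjusted over the list alone (camera adjusted p = 1.7e-12, and adjusted p = 0.12 with an estimated correlation). CCL5, a T cell chemokine, rose 17.9-fold and TNFAIP3, a feedback inhibitor of NF-kappa-B, 2.49-fold. Of 14 MHC class I antigen presentation genes, 13 rose and 1 did not pass, and 13 passed adjusted over the list alone (camera adjusted p = 6.9e-10, and adjusted p = 0.12 with an estimated correlation). HLA-B rose 2.62-fold, HLA-F 2.59-fold and B2M, the shared light chain, 2.04-fold to 3043 ± 74 CPM; HLA genes are similar in sequence and their shares of reads are uncertain. Of 11 leukocyte markers, 4 were measured and 3 rose (CD68, ITGAM and LCP1; 3 adjusted over the list alone), with CD68, a lysosomal protein gene, going from 19.6 ± 1.2 to 68.8 ± 1.8 CPM and ITGAM from 1.76 ± 0.23 to 4.36 ± 0.57 CPM. That list's call (camera adjusted p = 0.039, and adjusted p = 0.25 with an estimated correlation) ended without vector replicate 1 (0.072), vector replicate 2 (0.16) or circNCOR1 replicate 1 (0.091), and in 6 of 16 alternatives in all, over a range of 0.016 to 0.20.

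Stress and signalling genes rose in several lists. Of 22 immediate early and AP-1 genes, 16 rose, 1 fell and 5 did not pass, with 18 adjusted over the list alone (camera adjusted p = 6.9e-06, and adjusted p = 0.16 with an estimated correlation). KLF4, a transcription factor gene, rose 5.50-fold, DUSP1 1.82-fold and FOSL1 by a log2 change of 0.59, and the gene that fell was EGR1, 3.01-fold lower. Of 16 MAPK feedback genes, 11 rose and 5 did not pass, with 12 adjusted over the list alone (camera adjusted p = 0.00034, and adjusted p = 0.16 with an estimated correlation); SPRY2, a receptor signalling inhibitor, rose 5.05-fold and cyclin D1 gene CCND1 1.38-fold. Of 23 ATF4 and amino acid stress genes, 15 rose, 3 fell and 5 did not pass, with 18 adjusted over the list alone (camera adjusted p = 0.0044, and adjusted p = 0.15 with an estimated correlation). ATF3 rose 4.28-fold, GDF15 1.92-fold and ATF4 itself 1.72-fold, while CTH, SLC7A5 and DDIT4 were lower. Of 24 p53 target genes, 19 rose and 5 did not pass, with 20 adjusted over the list alone (camera adjusted p = 1.7e-07, and adjusted p = 0.17 with an estimated correlation). GADD45A rose 2.05-fold and CDKN1A, a cyclin-dependent kinase inhibitor, 1.48-fold. Of 25 apoptosis regulators, 16 rose, 2 fell and 7 did not pass, with 19 adjusted over the list alone (camera adjusted p = 0.00012, and adjusted p = 0.17 with an estimated correlation). The pro-apoptotic PMAIP1 (NOXA) rose 3.60-fold and the death receptor gene TNFRSF10A 1.99-fold, while CASP9 and BMF were lower; the BMF call ended when any 1 library other than circNCOR1 replicate 1 was left out (up to adjusted p = 0.15), and in 11 of 17 alternatives in all, with a range of 0.0066 to 0.27.

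The endoplasmic reticulum chaperone list stood at the threshold. Of 20 genes, 8 rose, 1 fell and 11 did not pass, with 9 adjusted over the list alone (camera adjusted p = 0.049, and adjusted p = 0.47 with an estimated correlation). HSPA5, the chaperone BiP, rose 1.30-fold and SEL1L was 1.38-fold lower. The call ended without vector replicate 1 (0.072), vector replicate 3 (0.066) or circNCOR1 replicate 1 (0.18), and in 9 of 16 alternatives in all, over a range of 0.030 to 0.18. Hypoxia and HIF targets counted 12 higher, 5 lower and 4 not passed of 21, with 17 adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.36 with an estimated correlation). PFKFB3, a glycolysis regulator, rose 1.55-fold and BNIP3L, a mitophagy receptor gene, was 1.48-fold lower, and the list's call ended without circNCOR1 replicate 1 (0.063) and in the FPKM test (0.065), over a range of 0.020 to 0.065. The KEGG HIF-1 signaling pathway, by contrast, was enriched among lower genes, with 39 of 92 where 21.2 would be expected (Fisher's exact test, adjusted p = 0.0018).

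Cell cycle genes were tested as separate lists for each phase, whose difference was not tested. Of 34 G2/M and mitosis genes, 28 fell and 6 did not pass, with 29 past the threshold adjusted over the list alone, and the median log2 fold change was -0.48 (camera adjusted p = 3.4e-14). Cyclin B1 gene CCNB1 was 1.64-fold lower (235 ± 6.2 against 143 ± 7.7 CPM), the mitotic kinase gene AURKA 1.57-fold lower and PRC1, a spindle midzone gene, 1.48-fold lower. This was the 1 list of 44 whose call held with an estimated correlation (adjusted p = 0.040). Calls were lost by lists with a correlation above the preset 0.01 and also by some below it. Lymphangiogenesis and angiogenesis factors, for example, had an estimated correlation of -0.030 and a camera adjusted p of 0.12. A call lost in that test is therefore not by itself a sign of correlated genes. Of 35 G1/S and DNA replication genes, 19 rose, 5 fell and 11 did not pass, with 25 adjusted over the list alone and a median log2 fold change of 0.11, or 0.072 without circNCOR1 replicate 1 (camera adjusted p = 0.0062, and adjusted p = 0.30 with an estimated correlation); E2F1 rose 1.43-fold, CDC6, a replication licensing gene, 1.40-fold and E2F7 by a log2 change of 0.68. Of 10 replication-dependent histone genes, 5 rose and 5 did not pass, with 6 adjusted over the list alone (camera adjusted p = 0.049, and adjusted p = 0.33 with an estimated correlation). H2BC8 rose 3.79-fold from 1.13 ± 0.20 CPM. Copies within a histone family are similar in sequence, so reads may be divided uncertainly between them. The histone call ended without vector replicate 1 (0.074), vector replicate 2 (0.056), circNCOR1 replicate 1 (0.087) or circNCOR1 replicate 2 (0.074), and in 10 of 16 alternatives in all, over a range of 0.020 to 0.087.

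The lists of ribosome biogenesis and ribosomal protein genes shifted in opposite directions, and their difference was not tested. Of 25 ribosome biogenesis and MYC target genes, 20 rose and 5 did not pass, with 21 adjusted over the list alone (camera adjusted p = 3.1e-07, and adjusted p = 0.12 with an estimated correlation); ODC1, the first enzyme of polyamine synthesis, rose 2.27-fold and the nucleolar protein gene NOP56 1.48-fold. Of 45 cytosolic ribosomal protein genes, 31 fell and 14 did not pass, with 33 adjusted over the list alone and a median log2 fold change of -0.18 (camera adjusted p = 3.3e-09, and adjusted p = 0.47 with an estimated correlation). RPLP0 was 1.53-fold lower, at 786 ± 21 against 1207 ± 10 CPM, and RPS3A 1.42-fold lower. Ribosomal protein genes have many processed pseudogenes, and how shared reads were counted is not given in the sources used here.

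In each of the energy metabolism lists, more genes fell than rose. Of 13 mitochondrially encoded genes, 11 fell and 2 did not pass, with 11 adjusted over the list alone (camera adjusted p = 1.1e-07, and adjusted p = 0.34 with an estimated correlation). MT-ATP6 was 1.43-fold lower and MT-CYB 1.41-fold lower, and mitochondrially encoded genes took 7.75% to 7.87% of counts in vector libraries and 5.94% to 6.4% in circNCOR1 libraries. Of 30 nuclear-encoded oxidative phosphorylation genes, 15 fell, 2 rose and 13 did not pass, with 17 adjusted over the list alone (camera adjusted p = 0.0033, and adjusted p = 0.48 with an estimated correlation). SDHC was 1.41-fold lower and NDUFV1 1.30-fold lower, while the 2 that rose were CYCS and NDUFA4, the latter losing its call without vector replicate 2 or 3 or circNCOR1 replicate 1 or 2 (up to adjusted p = 0.15) and in 9 of 17 alternatives in all (range 0.017 to 1.0). Of 19 glycolysis genes, 11 fell, 3 rose and 5 did not pass, with 14 adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.47 with an estimated correlation). GAPDH, often used as a reference gene, was 1.29-fold lower (1996 ± 13 against 1544 ± 71 CPM) and GPI 1.32-fold lower, and the 3 that rose were HK2, SLC2A1 and SLC16A3, a kinase and a pair of transporters. ACTB, another common reference gene, did not pass (2140 ± 29 against 2187 ± 12 CPM).

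Adhesion and bladder lineage genes moved in both directions. Of 24 integrin and focal adhesion genes, 13 fell, 4 rose and 7 did not pass, with 19 adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.47 with an estimated correlation). ITGB1 was 1.30-fold lower and PARVA lower by a log2 change of -0.59, while ITGA5, ITGA2, ITGA1 and BCAR1 rose, BCAR1 losing its call without vector replicate 1 or 2 or circNCOR1 replicate 1 or 3 (up to adjusted p = 0.16) and in 9 of 17 alternatives in all (range 0.0090 to 1.0). Of 13 basal and squamous bladder genes, 10 rose, 2 fell and 1 did not pass, with 12 adjusted over the list alone (camera adjusted p = 0.0075, and adjusted p = 0.16 with an estimated correlation). KRT17 rose 2.42-fold to 210 ± 7.3 CPM and CD44 1.40-fold, while KRT5 and EGFR were lower. Of 12 luminal and urothelial genes, 4 rose, 4 fell and 4 did not pass, with 8 adjusted over the list alone (camera adjusted p = 0.96); FOXA1 rose 2.07-fold and ERBB2 was 1.52-fold lower, and the test leaned up while median and mean leaned down. Of 31 extracellular matrix genes, 15 fell, 8 rose and 8 did not pass, with 23 adjusted over the list alone (camera adjusted p = 0.24, with a mean above 0 and a median below 0). PLAUR, the urokinase receptor gene, rose 3.13-fold, and the matrix metalloproteinase gene MMP9 rose 5.53-fold to 90.3 ± 9.7 CPM, while SPARC was 2.08-fold lower. Of 18 mesenchymal genes, 7 rose, 7 fell and 4 did not pass (15 adjusted over the list alone, camera adjusted p = 0.60), with NT5E 3.74-fold higher. Of 21 epithelial genes, 9 rose, 4 fell and 8 did not pass (13 adjusted over the list alone, camera adjusted p = 0.21), with CLDN4 1.75-fold and OVOL1 2.12-fold higher.

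**Figure D3:**
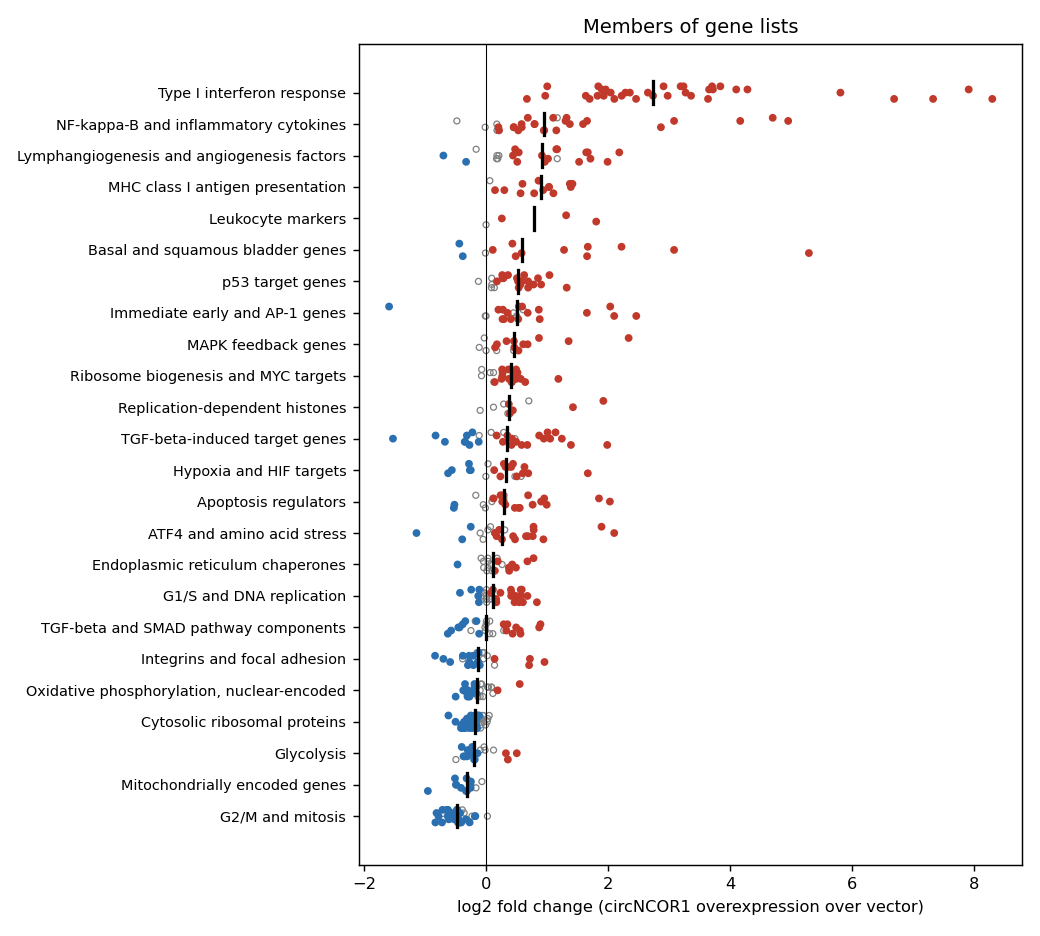
Log2 fold changes of the members of the gene lists that passed camera's test, with both TGF-beta lists; filled red points rose and filled blue points fell at an edgeR adjusted p under 0.05, open points did not pass, and black bars are list medians. The interferon list has a median of 2.74 and the G2/M list one of -0.48.

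The remaining lists did not pass. Counts of members higher, lower and not passed, with those adjusted over the list alone, were 7, 2, 7 and 9 for heat shock genes (camera adjusted p = 0.46) and 10, 4, 10 and 14 for cholesterol synthesis (0.41). They were 2, 4, 6 and 6 for fatty acid synthesis (0.35), where ACACA, the acetyl-CoA carboxylase gene, was 1.57-fold lower. NRF2 and glutathione genes gave 5, 7, 5 and 12 (0.41), with the ferritin gene FTH1 1.51-fold lower, and metallothioneins 3, 0, 1 and 3 (0.13). WNT targets gave 5, 2, 7 and 7 (0.41), with MYC higher by a log2 change of 0.68, the Notch pathway 7, 3, 5 and 11 (0.35), with NRARP 2.62-fold higher, and YAP and TAZ targets 10, 7, 3 and 17 (0.42). The hnRNP family gave 8, 11, 8 and 19 (0.36) and SR proteins and splicing factors 5, 7, 13 and 12 (0.66). The NCoR and SMRT corepressor complex gave 4, 3, 5 and 7 (0.41), with NR1D1, a clock repressor gene, 3.25-fold higher and HDAC4 at 5.35 ± 0.19 against 10.7 ± 0.97 CPM. Histone acetyltransferases and deacetylases gave 3, 9, 10 and 13 (0.13), autophagy and lysosome genes 8, 4, 11 and 12 (0.64) and circadian clock genes 6, 2, 7 and 8 (0.29). Fibroblast markers gave 0, 1, 1 and 1 (0.41), the lower gene being COL1A1. Endothelial markers gave 2, 1, 0 and 3 (0.88), with CDH5 2.55-fold lower and with KDR and ESAM higher, and their test leaned down while the median was above 0; the KDR and ESAM calls ended without vector replicate 2 (0.058 and 0.056), and the ESAM call without vector replicate 3 (0.059).

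Gene Ontology and KEGG terms were taken from the table's own annotation. Of 2669 terms, 118 were enriched among higher genes and 154 among lower genes (one-sided Fisher's exact test with Benjamini-Hochberg adjustment over terms and directions). Defense response to virus held 102 higher genes of 156, where 39.7 would be expected (adjusted p = 1.1e-22), and ribosome biogenesis 61 of 98, where 24.9 would be expected (adjusted p = 1.1e-11). Among lower genes, mitotic spindle organization held 60 of 123, where 28.3 would be expected (adjusted p = 1.3e-07), and cytoplasmic translation 42 of 86, where 19.8 would be expected (adjusted p = 2.2e-05).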

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

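The test of leukocyte transcripts was chosen after the leukocyte list's count had been seen, while the other tests in this part were set before their results.

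A signal outside the main measurement came from the FPKM columns. The transcript length implied by count over FPKM for NCOR1 was 4323 ± 619 nucleotides in vector libraries (4539, 4805 and 3625 in replicates 1, 2 and 3) and 3174 ± 14 in circNCOR1 libraries, a ratio of 0.734. The central 95% of 4503 genes with a mean count of at least 1000 and FPKM of at least 5 spanned 0.899 to 1.06, and 2 genes had a lower ratio than NCOR1. A change of the whole chromosomal region is argued against, since 21 tested genes within 1 Mb of NCOR1 had a median log2 fold change of -0.063. Reads from a part of the gene, such as plasmid-made exons of the circle, are a candidate explanation that the ratio of 0.734 met. The range across genes is of ratios of group means and does not cover the wide spread of NCOR1 among the vector libraries. Of these, replicate 3, at 3625, was the closest to the circNCOR1 libraries. A switch between NCOR1 isoforms was not tested, and circle and linear RNA were not told apart. The implied length depends on how the authors derived counts and FPKM, which the sources used here do not give. It also assumes that FPKM was scaled to the summed counts of each library.

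The interferon list rose with a median log2 fold change of 2.74. Library scaling is argued against, because the lowest median under 4 other scalings was 2.72. Leukocytes in the circNCOR1 cultures are argued against by 8 transcripts, of which ITGAM was highest at 4.36 ± 0.57 CPM, narrowly under the bound of 5, while PTPRC, MS4A1 and LYZ had 0 counts in the circNCOR1 libraries. CD68, which other cell types also express, stood at 68.8 CPM and was not among the 8. LCP1, which also rose, and CORO1A were on the leukocyte list but not among the 8 either. LCP1 had 2024, 1554 and 1554 counts in circNCOR1 replicates 1, 2 and 3 and 1614, 1705 and 1181 in vector replicates 1, 2 and 3. The bound of 5 CPM therefore covers the 8 and not the whole leukocyte list. Whether the circle itself or another property of the insert-bearing plasmid or its RNA raised these genes cannot be told apart, since 0 of the groups carried an insert-bearing plasmid that makes no circle.

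Ribosomal protein and nuclear-encoded oxidative phosphorylation genes, 75 in all, had a median log2 fold change of -0.17. Against 20 matched genes per member, the difference of medians was -0.18 when matched on transcript length (95% bootstrap interval -0.23 to -0.14), -0.18 on GC content (-0.23 to -0.14) and -0.12 on expression level (-0.17 to -0.08). These values argue against length, GC content or expression level as the whole cause, although the intervals treat the genes as independent and both list shifts were lost with an estimated correlation (adjusted p = 0.47 and 0.48). Counting of reads shared with pseudogenes was not tested and stays open, as does an effect of the overexpressed RNA.

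The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 6445 genes and 662 with at least a 2-fold change, and in edgeR the highest of the other 9 splits called 0 on either count, with 73 to 308 genes at an unadjusted p under 0.05. In both counts 1 of the 10 splits, the real one, gave a result as large. Each of the other 9 splits mixes both groups on each side, so the group difference adds to its spread and few calls are likely there. The 0 is therefore no measure of how many calls arise without a group difference.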

How the results depend on the processing

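The alternatives on FPKM, on a 1.2-fold change and on lists without NCOR1 were chosen after seeing the data. Over the others, counts of genes past the threshold stayed within 1.5 times the reported ones, from 5465 in DESeq2 to 6951 without circNCOR1 replicate 1. Of the 6445 called genes, DESeq2 kept 5280 in the same direction, limma-voom 6225 and total-count scaling 6052. The balance of directions varied with the scaling. It was 3852 higher and 2666 lower under total-count scaling, and 3207 higher and 3253 lower under upper-quartile scaling. The sources do not say whether the numbers 1 to 3 pair the libraries, and no pairing was seen. Correlations of deviations between libraries of the same number were -0.15 to 0.08, and 2 of 6 libraries correlated best with their own number. The replicate block gave 6106 genes.

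The test against a 1.2-fold change called 2637 genes, 1527 higher and 1110 lower, fewer because it asks for a larger change, and it ended the calls of CASP9, DDIT4, SLC16A3, COL1A1 and LCP1. In limma on log2(FPKM + 1), 1966 genes were lower, and genes past the threshold with at least a 2-fold change numbered 255. That scale understates the change of low genes, but the filter and the test differed too, so the cause of the lower number was not isolated. Camera with an estimated correlation called 1 list and fry, which does not compare a list with other genes, 38, against 22, and lists without NCOR1 gave 22. Terms among genes with at least a 2-fold change numbered 132 against 272.

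Among genes that did not pass, SMAD3 turned to 0.021 under total-count scaling and to 0.0062 in the FPKM test, and SMAD4 to 0.016 and to 0.23 (adjusted p = 0.018 in limma, range 0.018 to 1.0). With each library left out, log2 fold changes were -0.072 to 0.015 for SMAD3, -0.057 to 0.031 for SMAD4 and -0.017 to 0.043 for HNRNPL. For lists that did not pass, camera's direction turned for luminal genes at medians of -0.053 (upper-quartile scaling), -0.054 (DESeq2), -0.24 (no filter) and -0.037 (replicate block), and for endothelial markers at 0.97 (DESeq2) and 0.61 (no filter). It also turned for TGF-beta components at -0.00032 (no filter) and, in the FPKM test, for mesenchymal genes at 0.12 and SR proteins at 0.053. With each library left out, medians were -0.084 to -0.024 for luminal genes and 0.69 to 1.12 for endothelial markers. The cause was not tested. The effect of depth was not tested on its own. In simulated data at these depths, with only 200 genes changed, 30% of 1.2-fold changes were recovered over all genes.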

Other observations

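The test of the G1/S list below was chosen after its result was seen, and genes in this part were singled out after their values were seen.

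Keratinization genes were enriched among genes at least 2-fold higher, with 11 of 45 where 1.67 would be expected (one-sided Fisher's exact test, adjusted p = 9.1e-05). KRT6A, a keratin gene of stressed and wounded epidermis, rose 8.46-fold to 4.20 ± 0.54 CPM (log2 fold change 3.08, and 3.70 without vector replicate 1), KRT34 7.27-fold, KRT16 3.15-fold and PKP1, a desmosome gene, 2.71-fold. Most of these genes were at low levels. IGF2, a growth factor gene, rose 9.25-fold, from 1.14 ± 0.042 to 10.7 ± 1.9 CPM. Among matrix metalloproteinase genes, MMP1 rose 4.98-fold to 3.06 ± 0.70 CPM and MMP10 9.13-fold to 0.709 ± 0.14 CPM. The MMP10 fold rests on vector counts of 2, 0 and 2, and its log2 fold change of 3.19 was 2.56 without vector replicate 2.

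Cell adhesion was enriched among genes at least 2-fold lower, with 17 of 369 where 4.63 would be expected (adjusted p = 0.00048). BCAM, a laminin receptor gene, was 2.61-fold lower, at 46.6 ± 1.5 against 122 ± 8.0 CPM, and COL12A1, a fibril-associated collagen gene, 2.17-fold lower, at 146 ± 4.9 against 316 ± 21 CPM. LAMA4, a laminin chain gene, was 2.43-fold lower. Branched-chain amino acid degradation held 28 lower genes of 46, where 10.6 would be expected (adjusted p = 8.0e-06). BCKDHB and BCKDHA, subunits of the dehydrogenase that commits these amino acids to breakdown, were 2.18-fold and 1.63-fold lower, HIBADH 1.57-fold lower and ALDH2 1.95-fold lower.

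ENSG00000258465, which has no symbol in the table (chromosome 1, 160216800 to 160285130, minus strand), went from 4.54 ± 0.86 to 0.0889 ± 0.15 CPM, a log2 fold change of -5.31 (edgeR adjusted p = 3.8e-06). Its 6 circNCOR1 counts all came from replicate 1, and without that library none remained. It overlaps DCAF8 and PEX19 on the same strand, whose log2 fold changes were -0.30 and -0.20, so the division of reads among the 3 genes is uncertain.

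A smaller share of cycling cells is a hypothesis for the lower G2/M genes, and it would lower genes of both phases. The G1/S and DNA replication list had a median log2 fold change of 0.11 (95% bootstrap interval 0.01 to 0.41, which treats its genes as independent). The median was 0.072 without circNCOR1 replicate 1, and the list's upward shift was lost with an estimated correlation (adjusted p = 0.30). With 5 of its 35 genes lower and 19 higher, the list argues against a fall of both phases, and no rise of G1/S genes as a group is claimed. A shift between cycle phases was not tested.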
